A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

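Messenger RNA was profiled in the laboratory strain BY4741 of Saccharomyces cerevisiae, a haploid of mating type a, grown in rich medium with xylulose from an initial OD of 0.1 and harvested in log phase, per the labels' protocols. The labels list 18 libraries in 6 groups of 3. In each group RXT3 or PHO23 was either deleted or exchanged for the allele of strain T73 or strain CLIB215. Rxt3 and Pho23 are subunits of the large Rpd3 histone deacetylase complex. Per the labels' protocols, fragmented RNA was selected on poly-dT beads and copied with barcoded primers that carry unique molecular identifiers. Bowtie and build R64 are named in the submitters' processing notes, with no Bowtie version. How reads were assigned to genes and how molecules were counted are not given in the sources used here, and neither are the minimum for a value, the normalization and the centring.

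The authors deposited 1 table with 1 column of log values per group, which is read here as log2 values. Its column names carry no replicate number, so each column is treated as the authors' pooled value of a group, and no spread between replicates can be given for any of them. The base of the logarithm is not written in the table. Base 10 is improbable because a single ORF (YNL097W-A) spans 7.58 units, and base 2 and base e cannot be told apart from the values. Every difference below is therefore in log units read as log2. If the base were e, all differences, their order and the gene lists' percentiles would stand, and the size rule would mean a larger ratio. The table has 6701 rows, of which 51 have no ORF name and no value. Of the 6650 named ORFs, 4956 have a value in all 6 columns and 933 have none. The number of ORFs with a value runs from 5265 in the column labelled RXT3 deleted to 5391 in that of the RXT3 allele of T73. Depth per library is unknown, and the table gives no expression level.

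The values are centred per ORF. Among 208 ORFs with a value in 1 column only, 126 are exactly 0, and among 124 ORFs with 2 values the sum is 0 for 39 (tolerance 1e-06). Among the 4956 complete ORFs the sum is 0 for none. What was averaged for the centre, and whether any step followed the centring, cannot be read from the table. A value is not a change against unmodified BY4741, which is not analysed here. Only differences between columns are interpreted, because a centre that is common to the columns cancels in them. That the centre of an ORF was common to all columns is assumed here.

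Groups were taken from the sample titles, whose shared start is the column name. For 3 of the 6 groups the genotype field of the same samples names another strain. The samples titled as the RXT3 allele of T73 have the PHO23 deletion in that field. Those titled as the RXT3 allele of CLIB215 have the RXT3 allele of T73, and those titled as the PHO23 deletion have the RXT3 allele of CLIB215. Counts by the size rule, Pearson correlations between loci, medians and percentiles of the gene lists and differences of the genes in the text were recomputed with the columns named by the genotype field, while overlaps between loci were not.

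Before the data were examined, a quasi-likelihood count model on the 18 libraries, set tests on its fit and rules for named genes based on adjusted p-values were planned. None of these could be used, since the table holds neither counts nor replicates. The comparisons, the 34 gene lists and the naming by title or genotype field were also fixed then. What follows was chosen after the table had been seen. A difference between columns of at least 1 unit (2-fold if the base is 2) over the 4956 complete ORFs is counted, as a description of these columns and not a test. As a yardstick for single ORFs, the central 95% of the differences between the least different pair of columns was used, which runs from −0.82 to 0.82. This pair compares different strains, so the yardstick holds any real difference between them as well as noise. No p-value is given across genes, which are not replicates.

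For each gene list with at least 5 complete members, the median difference was placed among the medians of 10000 random lists of the same size. The random lists were not matched on expression, because the table holds no level. Percentiles of at most 0.1 or at least 99.9 are called extreme below. Over 30 such lists and 8 contrasts there are 240 medians, of which 0.48 would be extreme by chance if the medians, and the members within each list, were independent. Random lists hold unrelated ORFs, so a shift shared by a list's members can make its median extreme, whatever the source. Ribosome biogenesis was extreme even between the least different pair of columns (median 0.17, percentile 99.99). An extreme percentile is therefore a description and not a test of the edit. The remaining 4 lists were too small. The named genes are, for each of the 7 contrasts between columns, the 8 complete ORFs of the annotation with the largest difference in each direction, up to 4 members of each extreme list with the largest difference in the direction of its median, and RXT3 and PHO23. Other genes are said in the text to have been chosen after their values were seen. Gene names and coordinates come from the RefSeq annotation of assembly R64, in which 5962 of the ORF names were found.

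The resemblance of 2 columns was measured as the correlation across ORFs of their differences from 2 other columns, so that no column entered both differences, averaged over the 12 choices of those references. The steps were tested on simulated data built on the 4956 complete ORFs for the contrast of the PHO23 alleles. There, 99.5% of 200 ORFs changed by 2 units passed the size rule, as did 0.568% of the unchanged ORFs, with a simulated noise SD of 0.25 per column. That noise was independent between ORFs and below the SD of each real column over complete ORFs, 0.28 to 0.42. In the least different pair of columns 115 of the 4956 ORFs passed the rule. The 0.568% is therefore no false rate for the real columns. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives to the main settings were the genotype field as the source of the column names, all ORFs with a value in the columns compared, subtraction of column medians, restriction to annotated ORFs, and removal of the 5 ORFs in more than 1 list. Only the first of these was planned before the data were examined.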

Results

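The transcriptome of BY4741 was compared between strains that differed at 1 of 2 loci coding for subunits of the Rpd3L histone deacetylase complex, RXT3 and PHO23. At each locus the gene was deleted, replaced by its T73 allele or replaced by its CLIB215 allele. The cells grew on xylulose, a pentose sugar, and the series concerns natural variation in pentose fermentation. Each of the 6 strains is represented by a single pooled value per ORF, in centred log units read here as log2, although the base is not stated. No replicate error can therefore be attached to any value, and a difference between strains has no replicate check. Of 6650 ORFs, 4956 had a value in all 6 strains and entered the comparisons.

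The edited genes were examined first. RXT3 (YDL076C, chromosome IV, 320668 to 321552, minus strand, build R64) had a value of −0.05 in the column labelled RXT3 deleted, 0.11 with the T73 allele and 0.23 with the CLIB215 allele. In the PHO23 columns its values were −0.15 (deleted), 0.14 (T73) and −0.36 (CLIB215). The deletion was thus not visible at RXT3. Where the counted reads of RXT3 lie relative to the deleted part is not known, and reads outside it would check nothing. For these reasons the column is called the one labelled RXT3 deleted. PHO23 (YNL097C, chromosome XIV, 441366 to 442358, minus strand) had no value in the column labelled PHO23 deleted, which was the case for only 36 ORFs that had a value in every other column. It had values of 0.35 with its T73 allele and −0.88 with its CLIB215 allele, and of 0.12, −0.07 and −0.61 in the RXT3 columns labelled deleted, T73 and CLIB215. The column that the genotype field would name the PHO23 deletion is the one titled RXT3 with the T73 allele, where PHO23 had the value −0.07. PHO23 thus had no value where the titles place its deletion, and a value where the genotype field places it. This goes with the titles and argues against the genotype field for these columns. The name of the column titled RXT3 with the CLIB215 allele is not checked by PHO23.

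Of the 3 annotated genes with complete values on each side of RXT3, BRE1, AHK1 and VAM6 had the largest differences between the mean of the RXT3 columns and that of the PHO23 columns, and all 6 are named here after their values were seen. BRE1, a ubiquitin ligase gene (324047 to 326149), averaged 0.67 over the RXT3 columns and −0.35 over the PHO23 columns. AHK1 (326613 to 329567) averaged 0.69 and −0.30. VAM6 (316971 to 320120), a gene of vacuolar fusion, averaged 0.52 and −0.31, with −0.16 in the column labelled RXT3 deleted. MRK1 averaged −0.06 and −0.31, MDH3 0.06 and 0.05, and RPL31A, between RXT3 and BRE1, −0.03 and 0.13.

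**Figure D1:**
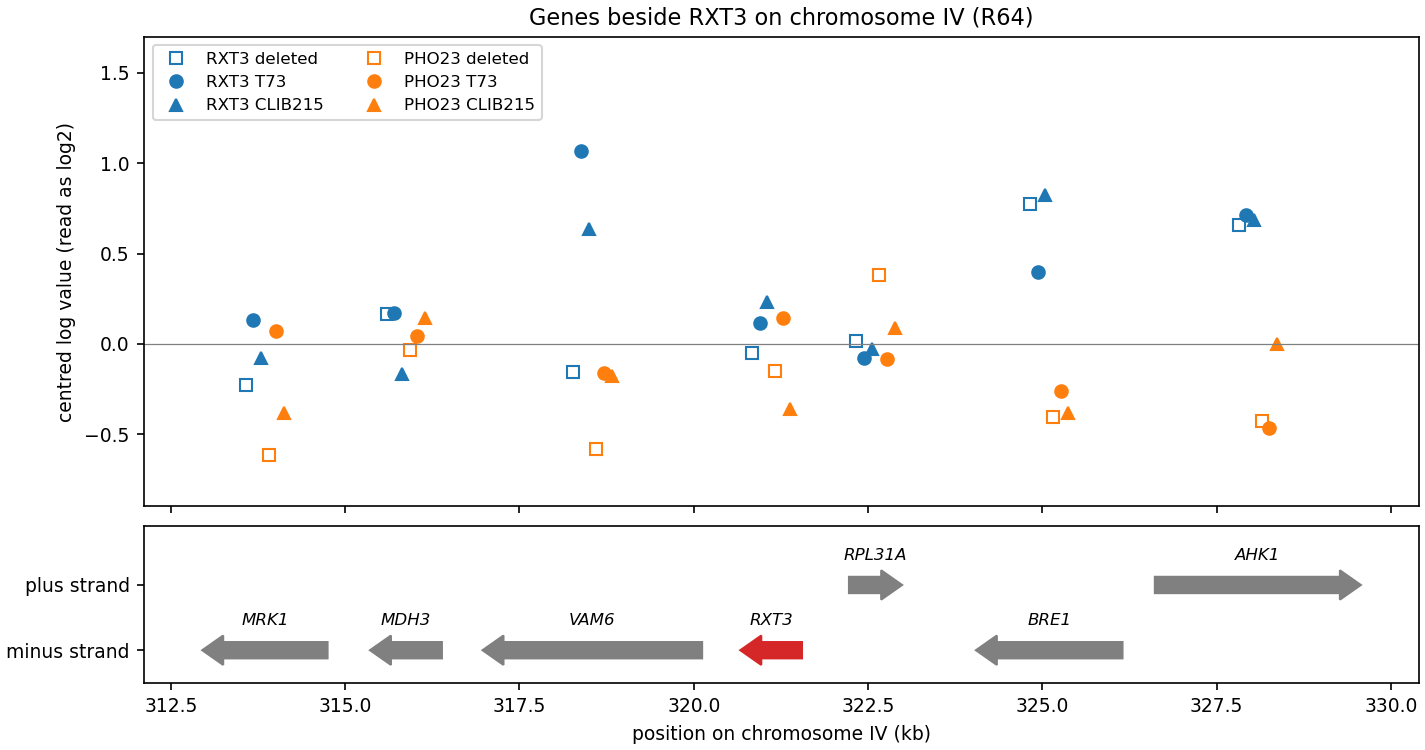
Map of the 7 genes around RXT3 on chromosome IV of build R64 (lower panel, arrows show strand, position in kb) and their pooled values in the 6 columns (upper panel, centred log units read as log2; squares columns labelled deleted, circles T73, triangles CLIB215, blue RXT3, orange PHO23). BRE1 and AHK1 were above 0 in the 3 RXT3 columns and below 0 in the 3 PHO23 columns, and RXT3 itself lay between −0.36 and 0.23.

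By the spread of their differences, 4 of the 6 columns lay closer together and 2 lay apart from them. The 3 RXT3 columns and the PHO23 T73 column differed from each other with SDs over ORFs of 0.391 to 0.426. The columns labelled PHO23 deleted and PHO23 CLIB215 differed from those 4 with SDs of 0.533 to 0.607, and from each other with an SD of 0.452. Their own values were also more spread over complete ORFs, with SDs of 0.421 and 0.422 against 0.282 to 0.319 in the other columns. A wider column by itself enlarges the SD of its differences. These SDs are across ORFs, which are not independent replicates.

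**Figure D2:**
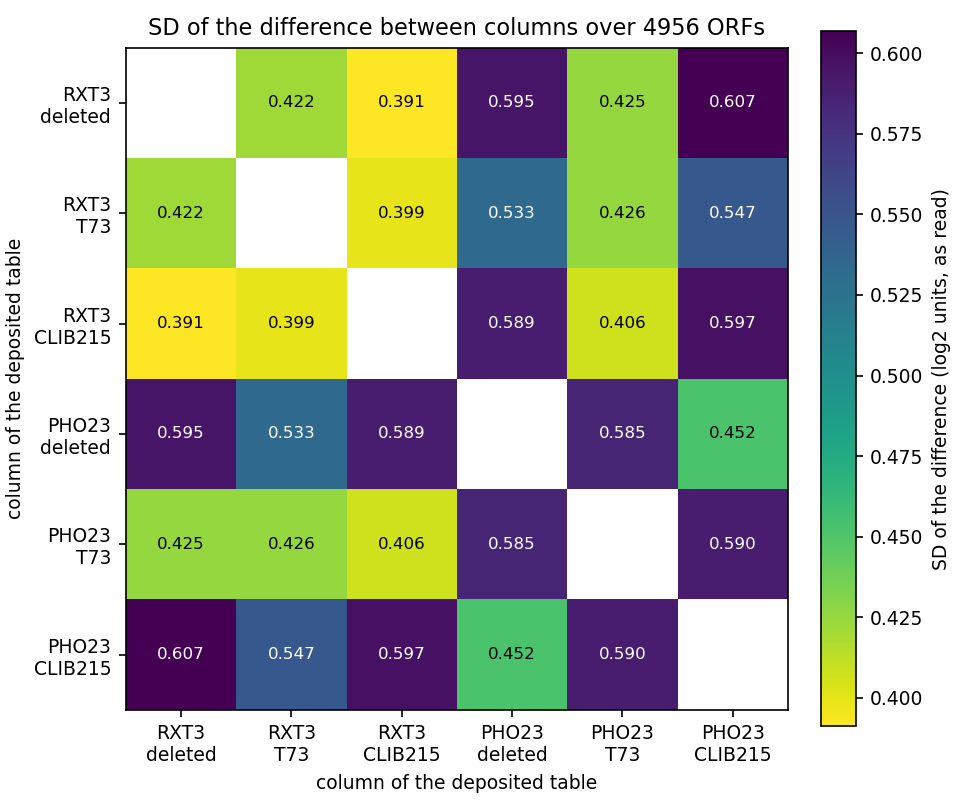
Standard deviation, over 4956 ORFs, of the difference between each pair of columns, in log units read as log2; each axis lists the 6 strains. The columns labelled PHO23 deleted and PHO23 CLIB215 lie 0.452 apart and at least 0.533 from each of the other columns.

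The 2 natural alleles of PHO23 were compared to ask what allelic variation at this locus does to expression. With the T73 allele, genes of gluconeogenesis and the glyoxylate cycle were higher than with the CLIB215 allele. PCK1 (YKR097W, chromosome XI, 631152 to 632801), the phosphoenolpyruvate carboxykinase, differed by 4.04, the malate synthase gene MLS1 by 3.46, the isocitrate lyase gene ICL1 by 3.07 and the fructose bisphosphatase gene FBP1 by 2.23. The small heat-shock gene HSP12 (YFL014W, chromosome VI, 107256 to 107585) was higher by 3.95, GCV1 of the glycine cleavage system by 2.95, the cell-wall iron gene FIT3 by 2.90, the kynureninase gene BNA5 by 2.70 and the cell-wall gene CWP1 by 2.59. Lower with the T73 allele were OPI3, a methyltransferase of phosphatidylcholine synthesis, at −2.39, and a series of genes for ribosome assembly and export, among them RRS1 at −2.03, ECM1 at −1.99 and RIX1 at −1.99. CPP3 (−2.19), GFD2 (−2.08), the tRNA methyltransferase gene TRM2 (−1.99) and the GTPase gene RAS1 (−1.88) completed the lowest genes.

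By list, 15 of 20 genes of ethanol and acetate use, glyoxylate cycle and gluconeogenesis were above 0, with a median of 0.77 (percentile 100 of random lists) and 8 members at 1 or more. In the opposite direction, 3 members were at −1 or less: ACS1 (−1.62), an acetyl-CoA synthetase gene, CAT2 (−1.29), a carnitine acetyltransferase gene, and CIT2 (−1.20), the peroxisomal citrate synthase gene, named after their values were seen. Ribosome biogenesis had 88 of 91 members below 0 and a median of −0.66 (percentile 0). Among its lowest members were NOP8 (−1.80), MPP10 (−1.74), the nucleolin gene NSR1 (−1.54) and RRP8 (−1.48). Of the cytosolic ribosomal protein genes, 132 of 137 were below 0, with a median of −0.42 (percentile 0). RPL22B (−1.15), RPS17B (−1.07), RPL8A (−1.03) and RPL18B (−0.85) were the lowest, but each has a near-identical paralog with which reads may have been shared. Stress response genes had 33 of 45 members above 0 and a median of 0.33, at percentile 99.89, just short of the bound.

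In total 220 ORFs were higher and 216 lower by at least 1 unit with the T73 allele. Of the 4956 ORFs, 15.1% lay outside the yardstick range of −0.82 to 0.82. The titles and the genotype field name both of these columns alike.

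**Figure D3:**
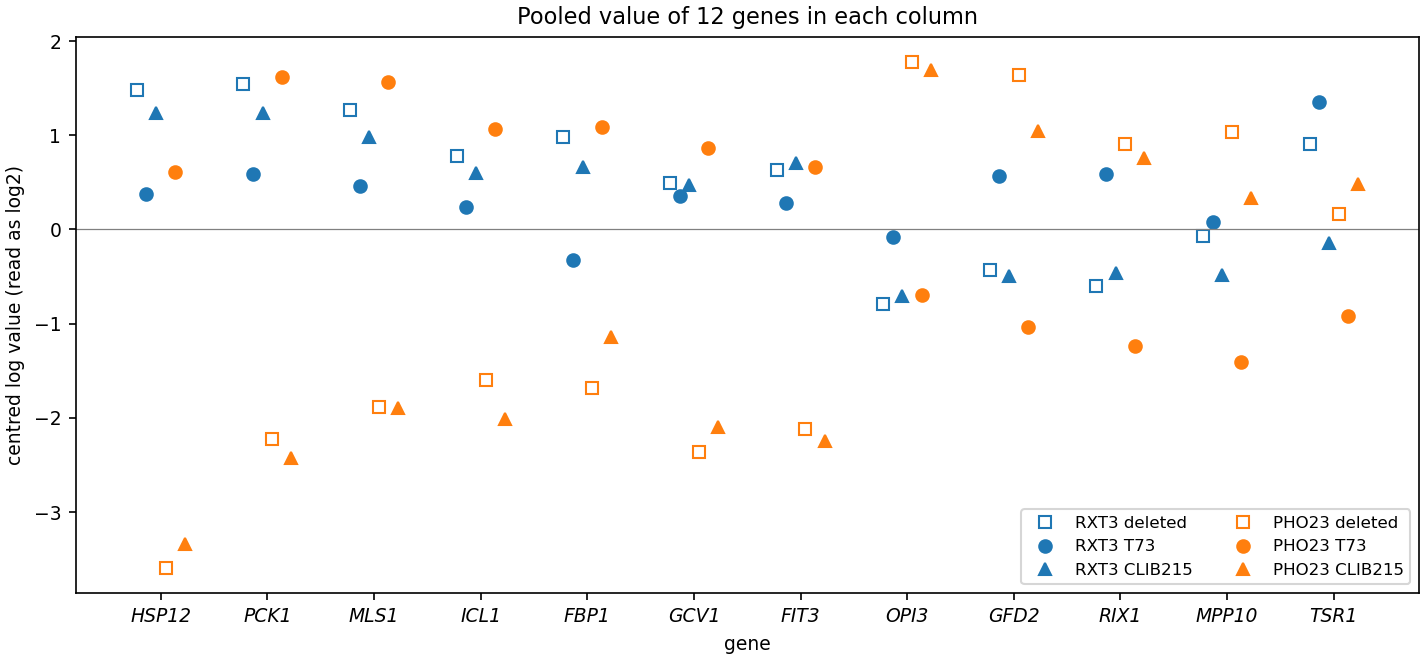
Pooled value (vertical axis, centred log units read as log2) of 12 genes named in the text (horizontal axis) in each of the 6 columns; squares are columns labelled deleted, circles T73 alleles and triangles CLIB215 alleles, blue for RXT3 and orange for PHO23, and there are no error bars because each value is a single pooled one. PCK1 stood at 1.62 with the PHO23 T73 allele, −2.43 with the PHO23 CLIB215 allele and −2.23 in the column labelled PHO23 deleted.

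The PHO23 deletion was compared with the T73 allele to ask how loss of the gene differs from carrying that allele. The genes lowest in the column labelled PHO23 deleted were HSP12 at −4.20, PCK1 at −3.85, MLS1 at −3.45, GCV1 at −3.22, FIT3 at −2.78, FBP1 at −2.77, ICL1 at −2.66 and CWP1 at −2.56, as deleted minus T73. Both this and the preceding comparison use the T73 column, so their differences share its deviations. The highest were GFD2 (2.68), OPI3 (2.48), MPP10 (2.44), the ribosome assembly gene FAF1 (2.17), RIX1 (2.14), the tRNA dihydrouridine synthase gene SMM1 (2.08), CPP3 (1.98) and the biotin synthase gene BIO2 (1.92).

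Here 6 lists were extreme. Ribosome biogenesis was higher in the deletion, with 88 of 91 members above 0, 30 of them by 1 or more, and a median of 0.69. NSR1 (1.53), KRI1 (1.48) and DBP7 (1.46) followed MPP10. Cytosolic ribosomal protein genes were higher for 133 of 137 members, with a median of 0.31. The genes of ethanol and acetate use, glyoxylate cycle and gluconeogenesis had a median of −0.86, with 10 of 20 at −1 or less and 3 at 1 or more. With the 21 members that had a value in both columns, this median was −0.56. Stress response genes were below 0 for 37 of 45 members, with a median of −0.36, and after HSP12 the lowest were DDR2 (−1.92), the glutathione peroxidase gene GPX1 (−1.78) and HOR7 (−1.17). Genes of the mitochondrial ribosome were below 0 for 59 of 87 members, with a median of −0.27, the lowest being MRP20 (−1.16), MRPL38 (−1.15) and MRPS8 (−1.01). The a-specific and pheromone response genes were below 0 for 16 of 19 members, with a median of −0.54, led by PRM5 (−1.49), AXL1 (−1.04), PRM4 (−0.91) and the G-protein gene STE4 (−0.83).

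By the size rule 224 ORFs were higher and 196 lower in the column labelled PHO23 deleted, and 13.9% lay outside the yardstick range. With columns named by the genotype field 151 ORFs passed, and all 6 list medians and 31 of the 34 named genes moved by over 1.5 times, 2 of these genes changing sign. The a-specific and pheromone list turned to 0.39 and the stress list to 0.02. The others shrank to 0.23 for ribosome biogenesis, 0.0014 for ribosomal proteins, −0.13 for ethanol and acetate use, glyoxylate cycle and gluconeogenesis, and −0.11 for the mitochondrial ribosome.

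**Figure D4:**
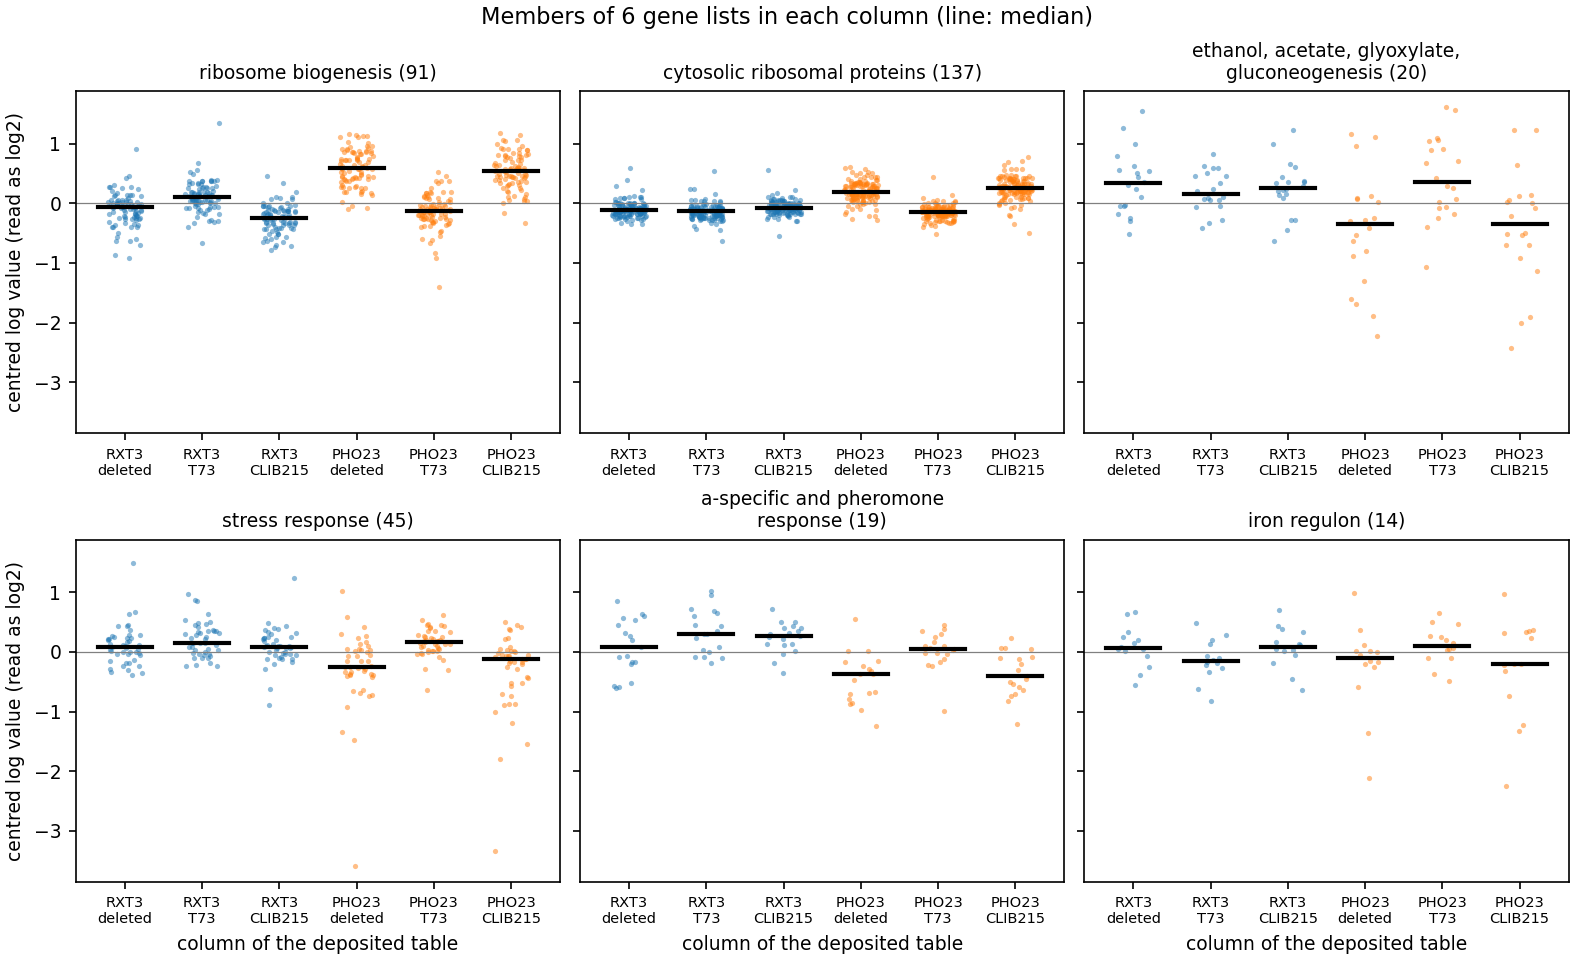
Values of the members of 6 gene lists (points; number of members in brackets) in each of the 6 columns (horizontal axis), in centred log units read as log2 (vertical axis), with the list's median as a line; blue marks RXT3 columns and orange PHO23 columns. The ribosome biogenesis median was 0.59 in the column labelled PHO23 deleted and 0.54 with the PHO23 CLIB215 allele, against −0.13 with the PHO23 T73 allele.

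Set against the CLIB215 allele, the PHO23 deletion showed fewer differences and no list was extreme. The median of ribosome biogenesis was 0.10 (percentile 94.1), and OPI3 differed by 0.09. The 8 genes highest with the T73 over the CLIB215 allele ran from −0.27 for GCV1 to 0.96 for BNA5, the only one of them outside the yardstick range, with PCK1 at 0.20, MLS1 at 0.01 and ICL1 at 0.41. FBP1 differed by −0.54. The largest differences, deleted minus CLIB215, were in genes of unlike function: the transcription factor gene ACA1 (−1.91), the sterol deacetylase gene SAY1 (−1.62), AFI1 (−1.57), RFC2 of replication factor C (−1.50), the cyclin gene SSN8 (−1.49) and the carnitine acetyltransferase gene YAT1 (−1.42) were lowest, with IES3 at −1.41 and DON1 at −1.35. The vacuolar carboxypeptidase gene CPS1 (1.98), PGS1 of mitochondrial phospholipid synthesis (1.80), the vacuolar transporter gene YPQ2 (1.77), GPB1 (1.68), MDM1 (1.64), KAR9 (1.60), SIA1 (1.51) and ASA1 (1.48) were highest. By the size rule 97 ORFs were higher and 62 lower, and 7.45% lay outside the yardstick range. If named by the genotype field, these groups differed in 337 ORFs, and 12 of the 16 named genes moved by over 1.5 times. Several lists were then extreme. Below 0 these were ribosome biogenesis (−0.41) and ribosomal proteins (−0.40). Above 0 they were ethanol and acetate use, glyoxylate cycle and gluconeogenesis (0.62) and stress response (0.35). Also above 0 were a-specific and pheromone genes (0.74) and thiamine and pyridoxine (0.73). OPI3 then differed by −1.77, PCK1 by 3.02, MLS1 by 2.36, GCV1 by 2.45, BNA5 by 2.90, ICL1 by 2.25 and FBP1 by 0.81.

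At RXT3 the T73 and CLIB215 alleles were compared with the same question as at PHO23. Ribosome biogenesis genes were higher with the T73 allele, with 83 of 91 members above 0, a median of 0.34 (percentile 100) and 4 members at 1 or more: TSR1 (1.49), NSA2 (1.28), UTP13 (1.11) and RRP12 (1.03). Iron regulon genes had 11 of 14 members below 0 and a median of −0.38 (percentile 0.02), but none of them at −1 or less. The lowest members were ISU2 (−0.86), the ferroxidase gene FET3 (−0.79), SMF3 (−0.60) and COT1 (−0.57). The only member past the size rule went the other way: the heme oxygenase gene HMX1 at 1.12, named after its values were seen. With the 18 members that had a value in both columns the iron median was −0.18. Single genes with the lowest values were HAT1, a histone acetyltransferase gene (−1.66), HDA1, a histone deacetylase gene outside Rpd3L (−1.46), the F-box gene UCC1 (−1.44), SLM1 (−1.41), the GTPase gene RSR1 (−1.36), RSB1 (−1.29), FAR8 (−1.25) and the peroxisomal import gene PEX7 (−1.25). The highest were the co-chaperone gene CNS1 (1.59), TSR1, SIP18 (1.49), the F-box gene MET30 (1.48), RRT1 (1.48), RPC17 of RNA polymerase III (1.46), SOM1 (1.40) and RQT4 (1.39).

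By the size rule 68 ORFs were higher and 41 lower with the RXT3 T73 allele, and 5.39% lay outside the yardstick range, so that single genes hardly stood out from the least different pair of columns. Naming the columns by the genotype field gave 457 ORFs, all 23 named genes moved by over 1.5 times or changed sign (21), and the medians turned to −0.85 for ribosome biogenesis and 0.11 for the iron regulon, and HMX1 to −0.76.

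Between the column labelled RXT3 deleted and the RXT3 T73 allele, ribosome biogenesis genes were lower in the former for 70 of 91 members, with a median of −0.19 (percentile 0), and PWP2 (−1.20), NSA2 (−1.04), NOP2 (−0.92) and RRP1 (−0.85) were lowest. The a-specific and pheromone response genes had 12 of 19 members below 0 and a median of −0.40 (percentile 0.01), with PRM5 at −1.53, the a-factor gene MFA1 at −0.83, the agglutinin gene AGA2 at −0.74 and the protease gene BAR1 at −0.69. Glycolytic genes were below 0 for 16 of 17 members, with a median of −0.30 at percentile 0.35, which was not extreme. The lowest single genes were the deubiquitinase gene OTU2 (−2.02), the allantoate permease gene DAL5 (−1.68), TDA1 (−1.54), PRM5, APC5 (−1.52), YHL008C (−1.52), PCL8 (−1.52) and TRM5 (−1.50). The highest were HDA1 (1.93), MUD1 (1.50), RSM25 (1.47), the polyamine transporter gene TPO1 (1.36), SAM37 (1.34), TMT1 (1.34), PEX7 (1.34) and FBP1 (1.31). The comparison of the RXT3 alleles uses the same RXT3 T73 column, so the differences in both share its deviations. HDA1, named in both, stood at −0.93 in that column. By the size rule 60 ORFs were higher and 83 lower, and 6.54% lay outside the yardstick range. The ribosome biogenesis median turned to 0.17 with columns named by the genotype field, the a-specific and pheromone median shrank to −0.13 and the glycolytic one to −0.01, and 20 of the 23 named genes moved by over 1.5 times, 1 of them changing sign.

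The column labelled RXT3 deleted and the RXT3 CLIB215 allele were the least different pair, with 49 ORFs higher and 66 lower by the size rule. Ribosome biogenesis genes were above 0 for 66 of 91 members, with a median of 0.17 (percentile 99.99), and TSR1 (1.05), UTP13 (0.88), UTP4 (0.78) and ENP2 (0.73) were highest. ROM1 (−1.74), ATG22 (−1.67), RAD57 (−1.50), YEL023C (−1.48), UGO1 (−1.46), AGE2 (−1.44), TDA1 (−1.44) and MSS18 (−1.42) were lowest. YOL107W (1.65), YNR068C (1.59), GPM3 (1.50), UAF30 (1.46), KTR5 (1.37), YNR065C (1.37), PRR1 (1.36) and TAF12 (1.32) were highest. By construction 248 of the 4956 ORFs lay outside the yardstick range. Under the genotype field's names 447 ORFs passed the size rule, 13 of the 20 named genes moved by over 1.5 times, 3 of them changing sign, and the ribosome biogenesis median turned to −0.73.

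The columns labelled as the 2 deletions were compared to ask whether loss of either subunit leaves the same transcriptome. HSP12 was higher by 5.07 where RXT3 was labelled deleted than where PHO23 was, followed by PCK1 (3.78), MLS1 (3.15), GCV1 (2.85), FIT3 (2.75), FBP1 (2.67), the decarboxylase gene FDC1 (2.54) and the metallothionein gene CUP1-1 (2.47), which has the near-identical copy CUP1-2. Lowest were OPI3 (−2.57), KEL2 (−2.44), GFD2 (−2.07), CPP3 (−2.05), GRC3 (−1.91), PWP2 (−1.88), ECM1 (−1.84) and SMM1 (−1.81). The column labelled PHO23 deleted also entered the comparison with the PHO23 T73 allele, so both comparisons share its deviations. HSP12 stood at −3.59 in it and at 1.48 in the column labelled RXT3 deleted.

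In this comparison 6 lists were extreme. Ribosome biogenesis had 84 of 91 members below 0 and a median of −0.73, with NMD3 (−1.57), NOP2 (−1.54) and NOG1 (−1.52) next to PWP2. Cytosolic ribosomal protein genes had 128 of 137 below 0 and a median of −0.30. Phospholipid and inositol synthesis had 15 of 17 below 0 and a median of −0.53, with CPT1 (−1.72), CHO2 (−1.16) and PIS1 (−0.95) after OPI3. The genes of ethanol and acetate use, glyoxylate cycle and gluconeogenesis had a median of 0.79, with 8 of 20 at 1 or more and 3 at −1 or less. The mitochondrial ribosome had 60 of 87 above 0 and a median of 0.29, led by MRP20 (1.11) and MRP10 (0.98). The a-specific and pheromone response genes had 14 of 19 above 0 and a median of 0.63, led by PRM4 (1.45), STE4 (1.33), the signalling regulator gene SST2 (1.27) and MFA1 (1.17). By the size rule 212 ORFs were higher and 235 lower, and 14.8% lay outside the yardstick range. The genotype field's names gave 143 ORFs and moved 34 of the 35 named genes by over 1.5 times, 5 of them changing sign. The a-specific and pheromone median then turned to −0.40 and the ribosomal protein median to 0.06. The other 4 shrank to −0.19 for ribosome biogenesis, 0.10 for ethanol and acetate use, glyoxylate cycle and gluconeogenesis, −0.12 for phospholipid and inositol synthesis and 0.07 for the mitochondrial ribosome.

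The effect of the T73 against the CLIB215 allele (T73 minus CLIB215) was finally set side by side for the 2 loci. The difference between the 2 effects, RXT3 minus PHO23, was largest as a list for ribosome biogenesis, with a median of 1.01 and 87 of 91 members above 0. Cytosolic ribosomal protein genes had a median of 0.34 and 121 of 137 above 0. The iron regulon (−0.76, 8 of 14 below 0) and the genes of ethanol and acetate use, glyoxylate cycle and gluconeogenesis (−0.68, 13 of 20 below 0) were also extreme, the iron regulon at −0.47 with its 15 members that had a value in the columns compared. Across ORFs, the 2 allele effects had a Pearson correlation of −0.154 and a Spearman correlation of −0.118. Of 68 ORFs higher with T73 at RXT3 and 216 lower with T73 at PHO23, 15 were shared, against 2.96 for independent lists. In the same direction 4 were shared among those higher and 3 among those lower, against 3.02 and 1.79. Of the 41 lower with T73 at RXT3 and 220 higher with T73 at PHO23, 3 were shared, against 1.82, so an overlap well above that of independent lists was seen in 1 of the 2 opposite directions. The columns labelled as deletions set against the T73 alleles gave a Pearson correlation of −0.141 between loci, and set against the CLIB215 alleles 0.015. Genes are not independent replicates, and no null spread could be drawn from library labels. In the difference between the effects 431 ORFs were higher and 392 lower by at least 1 unit. With columns named by the genotype field 523 passed, the correlation of the allele effects was 0.472 and the ribosome biogenesis median −0.19. The medians of the iron regulon (−0.06), ethanol and acetate use, glyoxylate cycle and gluconeogenesis (−0.11) and ribosomal proteins (0.12) shrank by over 1.5 times.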

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

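The tests in this part were chosen after the values they use had been seen, except that the correlation without listed genes was set down before it was computed. The difference between the loci was not tested, since each strain has 1 pooled value.

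Ribosome biogenesis genes went opposite ways with the alleles of the 2 genes. The T73 minus CLIB215 median was 0.34 at RXT3 and −0.66 at PHO23, and the median of the members' differences between the loci was 1.01. This list was also extreme between the least different pair of columns, RXT3 labelled deleted and RXT3 CLIB215 (median 0.17, percentile 99.99). An extreme median of this list is thus not particular to the allele comparisons. Of the 15 ORFs that were higher by at least 1 unit with T73 at RXT3 and lower by at least 1 unit with T73 at PHO23, 8 are among the named genes: GFD2 (difference between the loci 3.15), RRS1 (3.06), RIX1 (3.04), RRT1 (3.02), TSR1 (2.90), NSA2 (2.74), RPC17 (2.58) and MET30 (2.56).

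A shift of whole columns would move other ORFs about as much as the ribosome biogenesis list. The 4865 ORFs outside the list had a median difference between the loci of −0.051 (SD over ORFs 0.75), against the list's 1.01. However, the list was flagged because its medians stood out from random lists of ORFs in the same columns. The value is therefore no separate test of such a shift. Most members shared the shift, with 83 of 91 above 0 at RXT3 and 88 of 91 below 0 at PHO23. These counts belong to the description of the pattern and are no separate test of whether a few members carry it. The 81 of 91 (89.0%) that did both nearly follow from these counts and add little. The conflict between titles and genotype field bears on the pattern directly. With the genotype field's names both medians are below 0 and the median of the members' differences is −0.19. The missing value of PHO23 in the column titled PHO23 deleted, given above, argues against the genotype field's name for that column. Culture density at harvest and batch are not given in the labels, so a difference in growth between cultures may also lie behind it and stays open, as does an effect of the alleles themselves, which was not tested.

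The column labelled PHO23 deleted and the PHO23 CLIB215 allele resemble each other. With disjoint references their correlation across ORFs averaged 0.445 (range 0.386 to 0.504), the highest of the 15 pairs of columns, the next being 0.162. Noise that is unrelated between the columns and independent between ORFs would leave it near 0. This value is also the one that describes the pattern, so it is no separate test of such noise. A bias that shallow libraries share stays open, as depth is unknown. The listed genes alone do not carry the resemblance, as 4189 ORFs outside every list gave 0.376. The lists are incomplete: RRS1, ECM1 and RIX1, for example, are not in the ribosome biogenesis list. Whether unlisted genes of the same functions carry the resemblance is therefore left open. That the CLIB215 column holds deletion libraries is argued against by YNL097W-A, an ORF next to PHO23 by its systematic name, which differs by −7.13 (deleted minus CLIB215, yardstick −0.82 to 0.82), and by PHO23, which has a value only in the latter. Whether the CLIB215 allele has less function was not tested. PHO23 stood at −0.88 with its CLIB215 allele, against 0.35 with the T73 allele. A low value was not particular to that allele. In the RXT3 columns PHO23 stood at −0.61 (CLIB215), −0.07 (T73) and 0.12 (labelled deleted). Cultures or batches shared by the strains labelled PHO23 deleted and PHO23 CLIB215 are left open by the labels. The resemblance depends on the titles. With columns named by the genotype field, PHO23 deleted and PHO23 CLIB215 had a mean correlation of −0.044. The missing value of PHO23 in the column titled PHO23 deleted argues against that naming.

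Some genes beside RXT3 were higher in the RXT3 columns than in the PHO23 columns. Over the 3 annotated genes on each side with complete values the mean difference was 0.488. Only 0.966% of 4762 windows of the same kind (46 windows) had a mean as large in size. With columns named by the genotype field the mean was 0.033. Neither value decides between a chance run of neighbours, a wrong name of the columns and an effect of the edit, because both rest on BRE1, AHK1 and VAM6, the genes that prompted the pattern. Apart from these values, the missing value of PHO23 argues against a wrong name for the column titled PHO23 deleted. By the same difference of means MRK1 stood at 0.25, MDH3 at 0.0062 and RPL31A at −0.16.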

How the results depend on the processing

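Only the naming of columns by the genotype field was planned before the data were examined; the other alternatives were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number. Settings fixed beforehand that need counts or replicates (other size factors, count filters, other count models, thinning, leaving out replicates, other set tests, pseudocounts) were not run, as the table holds pooled log values, and depth is unknown.

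Subtracting column medians, restricting to annotated ORFs and, where it gives a value, using all ORFs with values in the columns compared left each comparison's count within 1.5 times and each correlation within 0.1 of its main value. The 24 extreme list medians kept their direction under these settings and without the 5 shared ORFs; 3 moved by over 1.5 times with all ORFs. Of 15 other list medians in the text, that of pentose phosphate and xylulose use (PHO23 alleles) moved to 0.04 with column medians subtracted, and that of the NAD list (PHO23 deleted against T73) to −0.84 without shared ORFs. Of 373 values of single genes, 20 moved by over 1.5 times or changed sign with column medians subtracted.

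With columns named by the genotype field, the PHO23 alleles keep their columns and values. The count for the column labelled RXT3 deleted against T73 was 115, within 1.5 times of 143, but from another pair of columns. Counts of ORFs past the size rule became 457 for the RXT3 alleles, 447 for RXT3 deleted against CLIB215, 151 for PHO23 deleted against T73, 337 for PHO23 deleted against CLIB215, 143 for the columns labelled as the 2 deletions and 523 for the locus difference. The correlation between loci became 0.472 for the alleles, −0.0089 for deleted against T73 and 0.415 for deleted against CLIB215, and the resemblance of PHO23 deleted with CLIB215 became −0.044. Of the 24 list medians 3, those of the PHO23 alleles, are identical, 12 moved by over 1.5 times without turning and 9 turned: ribosome biogenesis to −0.85 (RXT3 alleles), 0.17 (RXT3 deleted against T73), −0.73 (RXT3 deleted against CLIB215) and −0.19 (locus difference); ribosomal proteins to 0.057 (2 deletions); stress response to 0.015 and a-specific and pheromone genes to 0.39 (PHO23 deleted against T73) and −0.40 (2 deletions); the iron regulon to 0.11 (RXT3 alleles). Of the 24 extreme medians 6 stayed extreme in the same direction and 5 in the other, and 25 of all 240 medians were extreme. Of the 15 other medians 6 moved by over 1.5 times and 3 turned: phospholipid and inositol synthesis to −0.070 (PHO23 deleted against T73), pentose phosphate and xylulose use to −0.43 (RXT3 alleles) and ribosome biogenesis to −0.41 (PHO23 deleted against CLIB215). Chosen after their values were seen, BNA1, BNA5 and TNA1 (PHO23 deleted against T73) and XKS1, TKL1 and HMX1 (RXT3 alleles) changed sign. Of 176 values of named genes 133 moved by over 1.5 times or changed sign (32), none of them among the 25 for the PHO23 alleles. The cause is the construction of this setting, which gives 3 columns another name.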

Other observations

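Some lists lay outside the central 95% of random lists for PHO23 without being extreme, and a part of them is given here as values. With the T73 allele against the CLIB215 allele, 21 of 26 nuclear genes of the respiratory chain were above 0 (median 0.41, percentile 99.8), all 17 genes of ATP synthase (0.42, percentile 99.1) and all 9 genes of the list of NAD synthesis, nicotinic acid uptake and targets of the deacetylase Hst1 (0.66, percentile 99.8). Against the T73 allele, the column labelled PHO23 deleted had 13 of 30 lists outside that central range, 6 of them extreme. Nearest to the bound were the respiratory chain (median −0.37, percentile 0.25, 21 of 26 below 0), fatty acid oxidation and peroxisome (−0.48, percentile 0.26, 11 of 14 below 0), ATP synthase (−0.43, percentile 0.31, 17 of 17 below 0) and phospholipid and inositol synthesis (0.38, percentile 99.55, 13 of 17 above 0). The NAD list was farther from it, at −0.50 (percentile 1.2), with all 9 genes below 0. Named after their values were seen, BNA1 differed there by −1.43, BNA5 by −1.74 and the nicotinic acid transporter gene TNA1 by −1.29. With columns named by the genotype field, the differences between PHO23 deleted and T73 given in this paragraph shrank or turned. Not all differences did so: 151 ORFs passed the size rule, and ribosome biogenesis stayed extreme at 0.23. The medians of the lists above became −0.06 for the respiratory chain, −0.12 for fatty acid oxidation and peroxisome, −0.02 for ATP synthase, −0.07 for phospholipid and inositol synthesis and −0.09 for the NAD list, all inside the central range, and the 3 genes changed sign, to 1.16 for BNA1, 0.20 for BNA5 and 0.27 for TNA1.

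Genes of xylulose use and the pentose phosphate pathway did not stand apart as a list between the PHO23 alleles (median 0.09, percentile 57.5, 7 of 12 above 0) or between the RXT3 alleles (0.24, percentile 96.6, 10 of 12 above 0). The list lay outside the central 95% of random lists, without being extreme, for the column labelled RXT3 deleted against T73 (−0.26, percentile 2.08, 9 of 12 below 0) and for the columns labelled as the 2 deletions (RXT3 minus PHO23, −0.33, percentile 2.3, 7 of 12 below 0). Under the genotype field's names the median for the RXT3 alleles turned to −0.43 (percentile 0.78), and the last pair became −0.0014 (percentile 41.3) and −0.26 (percentile 2.3). The genes that follow were named after their values were seen. The xylulokinase gene XKS1 differed by 0.08 between the PHO23 alleles (0.02 after subtraction of column medians) and by 0.54 between the RXT3 alleles. The transketolase gene TKL1 differed by −0.22 and 0.11 in these comparisons. The minor isozyme genes GND2 and NQM1 were higher with the PHO23 T73 allele by 1.11 and 1.27, and with the RXT3 T73 allele by 0.65 and 0.86. For the RXT3 alleles the genotype field's names turn XKS1 to −0.39 and TKL1 to −0.71 and give 0.97 for GND2 and 1.47 for NQM1.

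The ORF YNL097W-A, which is not in the annotation used here, had values of 4.61 with the T73 allele and 4.16 with the CLIB215 allele of PHO23, −2.97 in the column labelled PHO23 deleted, and −1.77, −1.11 and −1.51 in the RXT3 columns labelled deleted, T73 and CLIB215. It had the largest spread between columns of any ORF.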
